A study of Homo sapiens and Mus musculus with 15 samples.

How the data were processed

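Messenger RNA was profiled in 15 libraries from 2 cell lines of chronic lymphocytic leukaemia (CLL), the human line MEC-1 and a mouse line, whose name is printed in the figures. Cells were treated in culture for 24 h with the solvent DMSO or with 50 nM FL3. The labels call FL3 a flavagline, a class of compounds known to bind the translation initiation helicase eIF4A and the prohibitins. Per the labels, libraries were made from 500 ng of total RNA with a kit that primes at the 3′ end of messenger RNAs (QuantSeq FWD), with unique molecular identifiers added. Such libraries give about 1 fragment per transcript, so values were not divided by transcript length.

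The deposited tables, 1 per line, hold raw counts per gene symbol, whole numbers that differ in total between libraries and were not normalised by the authors. Per the labels, the authors used FastQC, cutadapt 2.10, STAR 2.5.3a, UMI-tools 1.0.0 and featureCounts from Subread 2.0.0, with the builds GRCh38 and GRCm38. Their settings, the annotation release, the strand setting of the counting and whether reads with the same identifier were collapsed before counting are not given in the sources used here. A transcript that overlaps another gene on the opposite strand may therefore share its counts. Intervals on counts cover counting error only.

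Samples were grouped by line and treatment from their titles, giving 4 DMSO and 4 FL3 libraries of MEC-1, and 3 DMSO and 4 FL3 libraries of the mouse line. No source used here says that replicates were separate cultures, so p-values measure only the spread between these libraries. Choices of test, filter, gene lists, named genes and the variations reported below were made before the data were examined, except where the text says otherwise.

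Each line was fitted alone with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, with treatment as the only term. Library sizes were scaled by trimmed mean of M-values (TMM) factors, genes were filtered by filterByExpr (minimum count 10, minimum total count 15), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05 and no minimum fold. Adjusted p-values of genes in the text come from this test. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of the F statistic. Levels are CPM, counts scaled to a common library size with TMM factors, as mean and standard deviation (SD) of the replicates. Where a group held 1 to 3 counts of a gene in total, the ratio of counts per counted read is given in place of a fold, with its exact 95% interval (Clopper-Pearson).

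Gene lists, 27 in all, were written from general knowledge of B cells, of the compound class and of cell types that could be mixed in. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and adjusted over the lists tested. An adjusted p named as given with an estimated correlation comes from camera with the correlation estimated from the data. Each list is also described by how many members passed among all genes and when adjusted over the list alone. Members of some lists overlap, so the lists are not independent. Some genes and a list that were tested are not reported here; the counts of genes and lists include them.

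The difference in response between the lines was tested as an interaction in 1 edgeR fit over all 15 libraries, with TMM factors computed within each line. Genes were joined by symbol regardless of case, 1 to 1, which stands in for orthology, and had to be tested in both lines, leaving 8030 genes. A list was tested for a difference with camera on the interaction coefficient.

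The rule for named genes took, per line, the 6 highest and 6 lowest log2 fold changes among genes past the threshold with at least 10 CPM in the higher group and no overlap between FL3 and DMSO libraries, 16 genes fixed in advance, and up to 3 members of each list with the smallest p. For the difference it took the 5 highest and 5 lowest interaction coefficients with at least 10 CPM in the higher group of each line. Positions of human genes are those of GENCODE release 29 on GRCh38, counted from 1, in which 108 of 108 symbols named for MEC-1 or the difference matched 1 gene; positions in the mouse were not used here. The symbols MARCH1 and MARCH2, which spreadsheet software alters, were ambiguous and were left out of the naming and of the join between lines.

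Replicate numbers were checked for pairing by correlating, across genes, the deviations of libraries from their group mean. In the mouse line, DMSO and FL3 libraries of the same number correlated at 0.69, 0.24 and 0.21, so a fit with replicate number as a block was set beside the main values where it changed a call. FL3 replicate 4 of the mouse line has no DMSO partner, and it correlated at 0.65 with DMSO replicate 2. DMSO replicate 3 correlated at 0.23 with FL3 replicate 1, and DMSO replicate 1 at 0.17 with FL3 replicate 3. The other pairs of unlike number in the mouse line had negative values. Pairing by number is therefore not shown by these correlations.

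The procedure was tested on simulated data with the depth and the gene-wise spread of these libraries. Each gene was drawn separately, so an axis shared by many genes was not simulated. A far smaller share of genes was changed than passed in these libraries, which makes the adjusted threshold harder to reach. The shares recovered may therefore not hold for the real data. In MEC-1 it recovered 51.5% of simulated 1.5-fold changes, 85.1% of 2-fold and 100% of 4-fold changes. In the mouse line these shares were 8.96%, 43.9% and 90.8%, and for the difference between lines 16%, 55.4% and 95.8%. False calls numbered 3 in MEC-1, 7 in the mouse line and 22 for the difference. For the difference, they stood beside 17, 51 and 91 recovered genes at these folds, a larger false share than the adjusted threshold allows. In the mouse line, with 6, 29 and 59 recovered, the false share was slightly above it.

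Alternatives were other scalings (DESeq2 1.42.0 size factors in edgeR, library size alone), other tests (DESeq2, limma-voom, a test against a fold of 1.5 with glmTreat), no filter or a filter of at least 10 CPM, the replicate block, leaving out each library in turn, and, for lists, an estimated correlation and the self-contained test fry, which asks whether a list's genes move on balance in 1 direction. Chosen after seeing the data were thinning of counts to the smallest library and leaving out the ribosomal protein and mitochondrially encoded genes.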

Results

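Gene expression was measured by 3′ messenger RNA sequencing in MEC-1, an established human CLL B-cell line, and in a mouse CLL line, named in the figures, after 24 h with DMSO or 50 nM FL3. The MEC-1 groups had 4 DMSO and 4 FL3 libraries, and the mouse groups 3 DMSO and 4 FL3 libraries. Total counts per library were 2505666 to 3011384 in MEC-1 with DMSO, 2892112 to 4046306 in MEC-1 with FL3, 2874167 to 3617565 in the mouse line with DMSO and 1827812 to 3095194 in the mouse line with FL3. From these libraries 11188 genes were tested in MEC-1 and 10475 in the mouse line, and fold changes under 2 were recovered less often in the mouse line than in MEC-1 on simulated data.

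The first comparison asked how 24 h of FL3 changed transcript levels in MEC-1. With FL3, GZMB, which encodes the protease granzyme B, was 70.4-fold lower (log2 -6.14, SE 0.217, n = 4 per group), from 72.4 ± 4.91 to 0.991 ± 0.544 CPM (SD). ABCB1, the multidrug efflux pump, was 8.05-fold higher (log2 3.01, SE 0.115), rising from 22.3 ± 3.67 to 180.1 ± 8.09 CPM. Every one of the 77 ribosomal protein genes tested and all 13 mitochondrially encoded messenger RNAs were lower, and most enzymes of glycolysis fell with them. Altogether 7006 of 11188 genes (62.6%) passed the edgeR test, 3545 higher and 3461 lower with FL3, of which 857 and 916 changed more than 2-fold. With library size alone as the scaling, 7266 genes passed and 64.9% of them were higher, against 50.6% with TMM, as the median of all genes moved from 0.011 to 0.19 on the log2 scale.

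Beside ABCB1, the highest fold changes in MEC-1 were those of ARHGEF40, a guanine nucleotide exchange factor (10.7-fold higher, adjusted p = 3.53e-08, 10 counts over the DMSO libraries), EFNA1, an ephrin ligand (10-fold, adjusted p = 4.07e-08), and ZBTB10, a zinc finger protein (9.02-fold, adjusted p = 3.8e-13). They were followed by ACHE, acetylcholinesterase (7.43-fold, adjusted p = 6.35e-07), and GLIS2, a zinc finger transcription factor (7.29-fold, adjusted p = 1.83e-08). The lowest beside GZMB were SLC2A5, a fructose transporter (18.7-fold lower, adjusted p = 3.8e-13), NAPSA, an aspartic protease (17-fold, adjusted p = 1.75e-13), CXCL9, a chemokine (16.3-fold, adjusted p = 4.85e-14), KISS1R, the kisspeptin receptor (14.1-fold, adjusted p = 4.08e-11), and the small nuclear RNA RNU5F-1 (11.7-fold, adjusted p = 4.85e-14). In GRCh38, GZMB lies on chromosome 14 from 24630954 to 24634267 and ABCB1 on chromosome 7 from 87503633 to 87713323. ARHGEF40 lies on chromosome 14 (21070270 to 21090240), EFNA1 on chromosome 1 (155127460 to 155134857), ZBTB10 on chromosome 8 (80485619 to 80526265), ACHE on chromosome 7 (100889994 to 100896974) and GLIS2 on chromosome 16 (4314761 to 4339597). SLC2A5 lies on chromosome 1 (9035107 to 9088478), NAPSA on chromosome 19 (50358477 to 50365830), CXCL9 on chromosome 4 (76001275 to 76007488), KISS1R on chromosome 19 (917287 to 921015) and RNU5F-1 on chromosome 1 (44721786 to 44721902). ABCB1, ARHGEF40, GLIS2, GZMB, CXCL9, NAPSA, SLC2A5, ZBTB10 and RNU5F-1 overlap an annotated gene on the opposite strand, and how the counting treated strands is not given in the sources used here. RNU5F-1 is also not a messenger RNA, which the kit is made for, so its counts may not follow its level.

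Among genes fixed in advance, the transcript of the transcription factor MYC rose 2.16-fold in MEC-1 (log2 1.11, SE 0.192, adjusted p = 2.63e-05), from 39.6 ± 17.6 to 86.2 ± 12.3 CPM. The prohibitin genes fell, PHB by 0.66 and PHB2 by 0.32 on the log2 scale (adjusted p = 4.56e-06 and 0.00177). Of the cap-binding complex, EIF4G1, its scaffold, fell by 0.31 (adjusted p = 0.00464) and the helicase EIF4A2 rose 1.16-fold (adjusted p = 0.0198), while the cap-binding protein EIF4E had a log2 change of -0.20 that did not pass (adjusted p = 0.0529). EIF4E passed with DESeq2 size factors (adjusted p = 0.0405), with at least 10 CPM required (0.0171), without DMSO replicate 1 or FL3 replicate 3 (0.0352 and 0.0384; highest of the 8 values with a library left out 0.16) and without ribosomal protein and mitochondrially encoded genes (0.0456). Counts given to the helicase EIF4A1 fell by 1.42 on the log2 scale from 12.6 ± 2.1 CPM, but this gene, on chromosome 17 from 7572706 to 7579005, overlaps 5 others on the same strand, so its level is uncertain. The same doubt holds for EIF4A2 and, among genes named below, SNHG1 and SNHG7, which overlap 6, 7 and 4 others on their strand. It also holds, with fewer overlaps, for other human genes named in the comparisons here: RPL3 and NCL overlap 3, RPSA, HERPUD1 and IKZF3 2, and BBC3, BCL2, BTG1, CCND2, CDK4, COX8A, EIF3E, EIF4E, EIF4G1, EPOR, GPI, LDHA, MCL1, PDCD4, PHB2, RMI2, RPL32, TEDC1 and UQCR11 1 each. The apoptosis regulators BCL2 and BCL2L11, which encodes BIM, rose 1.77-fold and 3.13-fold (adjusted p = 1.7e-08 and 2.57e-07), and MCL1 rose 1.22-fold (adjusted p = 0.00876). TXNIP, a negative regulator of glucose uptake, rose 2.6-fold and PDCD4, an inhibitor of eIF4A, 1.34-fold. The cell cycle kinase CDK4 fell by 1.12 on the log2 scale. Changes of CCND2, which encodes cyclin D2, and of the kinase BTK were 0.05 on the log2 scale in each case and did not pass (adjusted p = 0.78 and 0.826). With library size alone, PHB2 and EIF4G1 no longer passed (adjusted p = 0.132 and 0.215). EIF4A2 no longer passed without DMSO replicate 2 or 4 or FL3 replicate 3 or 4 (adjusted p = 0.0522, 0.0554, 0.0665 and 0.0661; lowest of the 8 values with a library left out 0.0241), nor with at least 10 CPM required (0.0603).

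**Figure D1:**
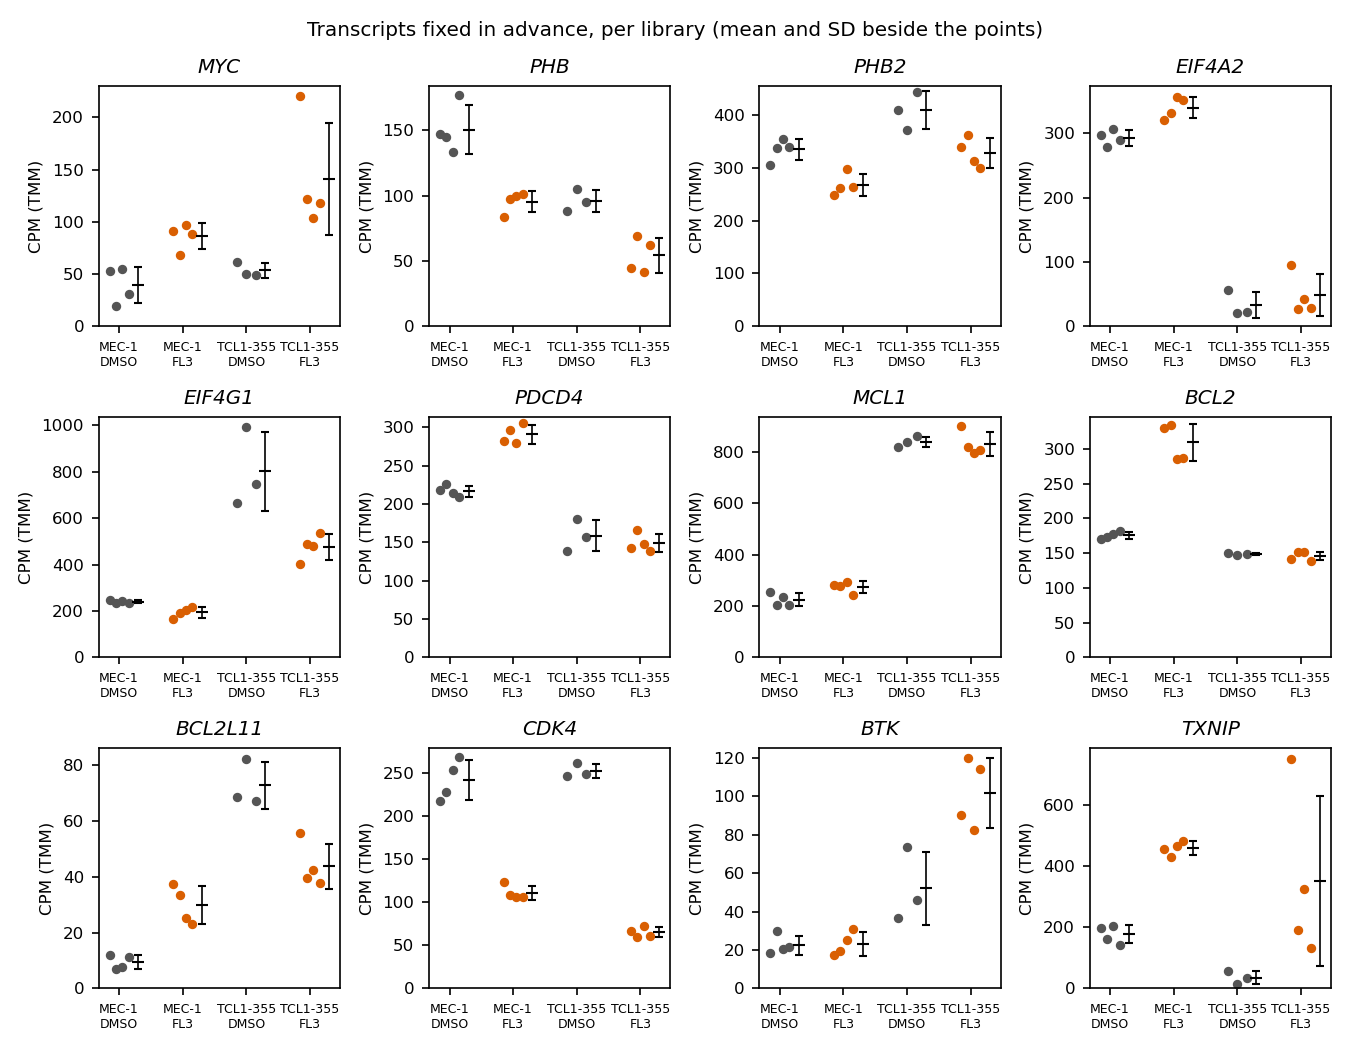
Normalised counts (CPM, TMM-scaled, 1 point per library) of 12 of the genes fixed in advance in each line and treatment, with the mean and SD drawn beside the points. MYC was higher with FL3 in both lines, and CDK4 fell by 1.12 in MEC-1 and by 1.95 in the mouse line on the log2 scale.

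Of the ribosomal protein genes, 77 of 77 fell with FL3 in MEC-1 (77 also when adjusted over the list alone; median log2 -0.82), for example RPL3 by 1.42, RPSA by 1.06 and RPL32 by 1.01 on the log2 scale. Camera on ribosomal protein genes gave adjusted p = 3.04e-20, and adjusted p = 0.182 with an estimated correlation. The 13 mitochondrially encoded messenger RNAs fell (13 adjusted over the list alone; median log2 -1.29), with MT-ND5 down 2.69-fold and MT-CO1 2.44-fold. Camera on these mitochondrial messengers gave adjusted p = 4.28e-08, and adjusted p = 0.182 with an estimated correlation. These genes' share of all counts, also read as a sign of RNA quality, was 6.17% ± 0.389 with DMSO and 2.95% ± 0.148 with FL3 (SD, n = 4 each), and that of ribosomal protein genes 12.6% ± 0.507 and 7.98% ± 0.49. In glycolysis, 22 of 26 genes fell and 2 rose (23 and 2 adjusted over the list alone), among them GPI, which isomerises glucose phosphate, 6.57-fold, LDHA, which makes lactate, 4.64-fold and TPI1 3.31-fold. Camera on glycolysis gave adjusted p = 1.19e-07, and adjusted p = 0.134 with an estimated correlation. Of the nuclear genes of the respiratory chain, 50 of 73 fell and 2 rose (51 and 2 adjusted over the list alone), such as UQCR11 2.28-fold and COX8A 1.8-fold. Camera on the nuclear respiratory chain gave adjusted p = 6.1e-08, and adjusted p = 0.186 with an estimated correlation. MYC targets fell in 37 of 46 cases and rose in 5 (38 and 5 adjusted over the list alone; median log2 -0.72), including the chaperone HSPD1 2.46-fold and thymidylate synthase TYMS 2.72-fold. Camera on MYC targets gave adjusted p = 1.4e-07, and adjusted p = 0.0796 with an estimated correlation. Ribosome assembly genes were mixed, with 24 of 49 lower and 8 higher (25 and 8 adjusted over the list alone), and nucleolin NCL, nucleophosmin NPM1 and NHP2 fell 1.97-fold, 2.1-fold and 3.11-fold. Camera on ribosome assembly gave adjusted p = 0.0136, and adjusted p = 0.29 with an estimated correlation. Translation initiation factors and related genes went both ways, 14 of 45 higher and 22 lower (15 and 24 adjusted over the list alone, camera adjusted p = 0.209). The initiation factor subunits EIF3I and EIF3E were down 2.03-fold and 1.86-fold.

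Immediate early genes, short-lived transcripts, rose in 19 of 25 cases and fell in 3 in MEC-1 (19 and 3 adjusted over the list alone), led by the transcription factors KLF6 (3.59-fold) and JUN (4.48-fold) and the antiproliferative BTG1 (2.19-fold). Camera on immediate early genes gave adjusted p = 0.00145, and adjusted p = 0.134 with an estimated correlation. Substrates of nonsense-mediated decay rose in 24 of 35 cases and fell in 6 (24 and 6 adjusted over the list alone), with the snoRNA host genes SNHG1 and SNHG7 up 2.43-fold and 2.62-fold. Camera on nonsense-mediated decay substrates gave adjusted p = 0.00154, and adjusted p = 0.134 with an estimated correlation. Of the list of the BCL2 family and other apoptosis regulators, 12 of 19 rose and 3 fell (12 and 3 adjusted over the list alone). The pro-apoptotic PMAIP1 (2.48-fold) and BBC3 (3.29-fold) were among those that rose. Camera on that list gave adjusted p = 0.0113, and adjusted p = 0.134 with an estimated correlation. Endoplasmic reticulum chaperone genes rose in 15 of 28 cases and fell in 3 (15 and 3 adjusted over the list alone), such as DNAJB9 5.41-fold and HERPUD1, which acts in protein degradation there, 2.06-fold. Camera on endoplasmic reticulum chaperones gave adjusted p = 0.0128, and adjusted p = 0.592 with an estimated correlation. Cytosolic chaperones fell in 17 of 26 cases and rose in 3 (18 and 3 adjusted over the list alone), with HSP90AA1 down 3.5-fold. Camera on cytosolic chaperones gave adjusted p = 0.00154, and adjusted p = 0.0936 with an estimated correlation. Targets of ATF4 were split, 14 of 32 higher and 7 lower (14 and 7 adjusted over the list alone; camera adjusted p = 0.502): ATF4 itself rose 2.71-fold and PPP1R15A, a phosphatase subunit, 3.25-fold, while PSAT1, of serine synthesis, fell 3.7-fold.

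DNA replication genes fell in 32 of 55 cases and rose in 13 in MEC-1 (32 and 14 adjusted over the list alone), with the uracil glycosylase UNG down 3.37-fold and the replication licensing factor CDC6 up 2.19-fold. Camera on DNA replication gave adjusted p = 0.0284, and adjusted p = 0.738 with an estimated correlation. This list no longer passed without FL3 replicate 3 or 4 (adjusted p = 0.076 and 0.0797; lowest of its alternatives with the preset correlation 0.0105). Mitotic genes showed no common direction, 11 of 51 higher and 10 lower (11 and 10 adjusted over the list alone; camera adjusted p = 0.937), with the mitotic activator CDC20 up 1.99-fold and securin, PTTG1, down 1.78-fold. B-cell receptor genes were 9 higher and 12 lower of 29 (the same numbers adjusted over the list alone; camera adjusted p = 0.788), and their median (0.08) differed in sign from their mean (-0.09) and from the test. The receptor subunit CD79A and the co-receptor proteins CD81 and CR2 fell by 0.85, 0.75 and 0.78 on the log2 scale. B-cell identity genes were 5 higher and 11 lower of 29 (the same adjusted over the list alone; camera adjusted p = 0.403), with VPREB3 6-fold and the IgE receptor FCER2 2.66-fold lower and the transcription factor IKZF3 1.84-fold higher. Plasma-cell genes were 5 higher and 7 lower of 16 (5 and 8 adjusted over the list alone; camera adjusted p = 0.815), with a median of -0.22 against a mean of 0.02, and the surface receptor SLAMF7 rose 1.83-fold. Targets of NF-kappaB were 16 higher and 10 lower of 34 (17 and 11 adjusted over the list alone; camera adjusted p = 0.414), among them the inhibitor NFKBIE (5.41-fold higher) and the chemokines CCL22 and CXCL10 (3.05-fold and 5.55-fold lower). ERK feedback genes were 8 higher and 3 lower of 13 (the same adjusted over the list alone; camera adjusted p = 0.341), with the inhibitor SPRED1 up 3.28-fold. Sterol synthesis genes were 6 higher and 6 lower of 22 (the same adjusted over the list alone; camera adjusted p = 0.663), with mevalonate kinase, MVK, up 3.1-fold. Interferon-stimulated genes were 8 higher and 5 lower of 24 (8 and 4 adjusted over the list alone; camera adjusted p = 0.502), with the RNA sensor IFIH1 up 3.22-fold and OAS3 down 1.92-fold.

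Markers of other cell types were also read in MEC-1. T and NK cell markers fell in 8 of 10 cases and rose in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.134 with an estimated correlation), for example the kinase LCK 2.89-fold, perforin, PRF1, 2.1-fold and the T-cell receptor constant gene TRAC 1.55-fold, from 241.4 ± 20.4 CPM. With at least 10 CPM required, this list no longer passed (adjusted p = 0.197; lowest of its alternatives with the preset correlation 0.00461). Of the myeloid markers 0 passed the filter, of 3 red-cell and platelet markers 2 fell (2 adjusted over the list alone), and 2 of 2 stromal markers rose (2 adjusted over the list alone), COL1A1 4.26-fold and ACTA2 1.64-fold; lists this small were not tested as lists. With library size alone, the red-cell gene EPOR, which had not passed (adjusted p = 0.106), passed as higher (0.0228). In all, 14 of 24 lists passed with the preset correlation, 5 higher and 9 lower, and with an estimated correlation 0 passed in camera, 8 having an unadjusted p under 0.05. With fry, 20 lists passed. Of the 35 splits of these 8 libraries into equal groups, the real one included, 4 gave at least as many lists. Splits that exchange 1 library per group, which keep part of the FL3 contrast, gave 9 to 15, and the 18 evenly mixed ones at most 9. How many lists chance alone would give cannot be read from these splits, so chance is not excluded.

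**Figure D2:**
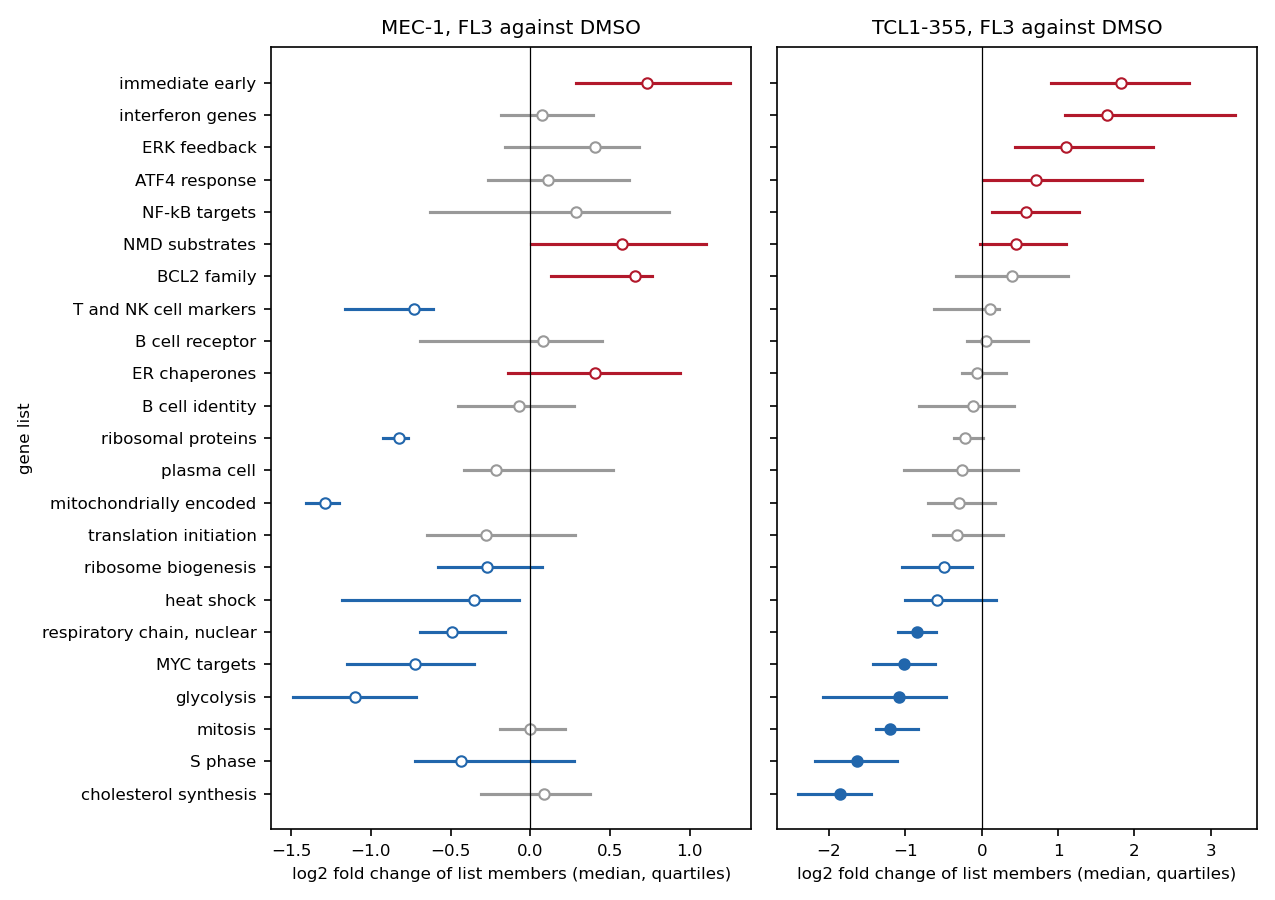
Median log2 fold change (FL3 over DMSO, dots) with quartiles (lines) of the gene lists described in the text, in MEC-1 and the mouse line; the log2 axes of the panels differ in range. Red and blue mark lists past the camera threshold with the preset correlation (higher and lower), grey marks the others, and filled dots, 0 in MEC-1 and 6 in the mouse line, also passed with an estimated correlation.

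The second comparison asked the same of the mouse line. With FL3, Ptgir, the prostacyclin receptor, was 87.7-fold higher (log2 6.45, SE 0.278, n = 3 DMSO and 4 FL3), from 1.69 ± 0.577 to 150 ± 29.5 CPM (SD), and the immediate early transcription factor Jun 31.3-fold (log2 4.97, SE 0.151). Of the 24 sterol synthesis genes tested, 22 fell. DNA replication and mitotic genes fell in 51 of 55 and 46 of 51 cases. Altogether 5548 of 10475 genes (53%) passed the edgeR test, 2837 higher and 2711 lower, of which 1442 and 1393 changed more than 2-fold.

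Of the named extremes in the mouse line, the predicted gene Gm20658 rose 70.2-fold (5 counts over the DMSO libraries; adjusted p = 1.99e-06), and Endou, an endoribonuclease, Ankle1, a nuclease, and Lipg, endothelial lipase, fell 30.9-fold, 27-fold and 23.1-fold (adjusted p = 3.58e-06, 4.4e-06 and 4.59e-05). Several others were too rare in a group for a fitted fold. The interferon-induced Ifit1 had 1 count over the DMSO and 312 over the FL3 libraries, a ratio per counted read of 316 (95% exact interval 56.3 to 12500). The ratio was 148 (26.1 to 5880) for the MAP kinase phosphatase Dusp8, 127 (22.3 to 5040) for Cdc42ep2, an effector of the GTPase Cdc42, and 102 (17.9 to 4080) for Spsb1, a ubiquitin ligase adaptor. In the other direction, DMSO over FL3, it was 179 (31.7 to 7100) for the ciliary gene Rsph1, 36.9 (12.3 to 182) for the kinase-like Rps6kl1 and 34.9 (11.6 to 172) for Pik3cg, a catalytic subunit of phosphoinositide 3-kinase. These 7 genes passed the edgeR test, with adjusted p from 5.47e-06 (Rsph1) to 7.66e-05 (Pik3cg).

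Of the genes fixed in advance, Myc rose 2.63-fold in the mouse line (log2 1.40, SE 0.257, adjusted p = 0.00139), from 53.8 ± 7.13 to 140.9 ± 52.9 CPM. Txnip rose 9.99-fold (SE 0.654 on the log2 scale, adjusted p = 0.00202), and its log2 change of 3.32 was 2.63 without FL3 replicate 1. Cdk4 fell 3.87-fold, Phb 1.78-fold, the initiation factors Eif4e and Eif4g1 1.63-fold and 1.68-fold, and Bcl2l11 1.65-fold (adjusted p = 2.72e-06, 0.00432, 0.000431, 0.00311 and 0.00488). Btk rose 1.95-fold (adjusted p = 0.00726). Phb2 fell by 0.32 and Ccnd2 rose by 0.44 on the log2 scale (adjusted p = 0.0455 and 0.048), each close to the threshold. Phb2 no longer passed without DMSO replicate 1 or 3 (adjusted p = 0.0928 and 0.175) or FL3 replicate 1, 3 or 4 (0.0687, 0.123 and 0.0627), with a lowest value of 0.0229 on leaving a library out, nor with no filter (0.0767) or thinned counts (0.0803). Ccnd2 no longer passed without DMSO replicate 1 or 3 (adjusted p = 0.13 and 0.121) or FL3 replicate 1, 2, 3 or 4 (0.0563, 0.109, 0.0695 and 0.152), with a lowest value of 0.00852, nor with library size alone (0.0742), DESeq2 size factors (0.0607), at least 10 CPM required (0.0695) or ribosomal protein and mitochondrially encoded genes left out (0.0645). Eif4a1 and Eif4a2 did not pass (log2 -0.39 and 0.58, SE 0.57 and 0.492, adjusted p = 0.595 and 0.344); with replicate number as a block, Eif4a2 passed (log2 0.73, adjusted p = 0.000473). On leaving out 1 library without a block, Eif4a2 ran from 0.0091 to 1.205 on the log2 scale and did not pass (adjusted p from 0.0592 to 0.987). Pdcd4, Mcl1 and Bcl2 had log2 changes of -0.09, -0.01 and -0.03 (adjusted p = 0.567, 0.926 and 0.816).

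DNA replication genes of the mouse line fell in 51 of 55 cases (53 adjusted over the list alone; median log2 -1.63), such as the helicase subunit Mcm3 6.62-fold, thymidine kinase Tk1 5.52-fold and Tyms 5.26-fold. Camera on DNA replication gave adjusted p = 5.74e-17, and adjusted p = 0.0064 with an estimated correlation. Mitotic genes fell in 46 of 51 cases (46 adjusted over the list alone; median log2 -1.20), with Hmmr, a spindle protein, down 4.95-fold, Cdca3 4.8-fold and the kinetochore gene Nuf2 3.73-fold. Camera on mitotic genes gave adjusted p = 3.91e-13, and adjusted p = 0.0093 with an estimated correlation. Sterol synthesis genes fell in 22 of 24 cases (22 adjusted over the list alone; median log2 -1.85), with Acat2 down 11-fold and Msmo1 4.35-fold. Camera on sterol synthesis gave adjusted p = 6.79e-11, and adjusted p = 0.0484 with an estimated correlation. Nuclear genes of the respiratory chain fell in 56 of 72 cases (56 lower and 1 higher adjusted over the list alone), for example Uqcr11 2.98-fold, Ndufs6 2.81-fold and Cox6a1 2.34-fold. Camera on the respiratory chain list gave adjusted p = 1.37e-11, and adjusted p = 0.0064 with an estimated correlation. MYC targets fell in 37 of 46 cases and rose in 3 (38 and 3 adjusted over the list alone; median log2 -1.02), with the nucleotide kinase Nme1 down 5.06-fold and Ldha 4.84-fold. Camera on MYC targets gave adjusted p = 7.45e-09, and adjusted p = 0.0064 with an estimated correlation. Glycolysis genes fell in 17 of 24 cases and rose in 4 (17 and 4 adjusted over the list alone), with pyruvate kinase Pkm down 6.08-fold and hexokinase Hk2 4.08-fold. Camera on glycolysis gave adjusted p = 0.000709, and adjusted p = 0.0484 with an estimated correlation. Ribosome assembly genes fell in 27 of 50 cases and rose in 2 (29 and 2 adjusted over the list alone), with Rrp9 and Tcof1 down 4.06-fold and 2.18-fold and Ubtf, a factor of RNA polymerase I, up 2.64-fold. Camera on ribosome assembly gave adjusted p = 5.68e-05, and adjusted p = 0.208 with an estimated correlation.

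Ribosomal protein genes fell in 7 of 76 cases in the mouse line (2 adjusted over the list alone; median log2 -0.22; camera adjusted p = 0.251), with Rpl3 down 1.7-fold and Rpl6 1.47-fold. Without DMSO replicate 2, in which these genes took 7.64% of counts against 10.1% and 11.9% in the other DMSO libraries, the list passed as lower (adjusted p = 0.00171); they took 8.92% ± 1.01 of counts with FL3 (SD, n = 4). Of 13 mitochondrially encoded messenger RNAs of the mouse line, 7 passed the filter. Of these 7, 3 fell (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.432), mt-Nd1 1.69-fold, mt-Nd2 1.57-fold and mt-Nd6 4.68-fold. Translation initiation factors and related genes were 7 higher and 17 lower of 46 (7 and 17 adjusted over the list alone, camera adjusted p = 0.133). Eif3b was down 1.96-fold and the RNA helicase Ddx6 up 3.09-fold. Cytosolic chaperones fell in 12 of 22 cases and rose in 4 (12 and 4 adjusted over the list alone), with Hspe1 and the immunophilin Fkbp4 down 2.84-fold and 2.34-fold and Hspa4l up 3.6-fold. Camera on cytosolic chaperones gave adjusted p = 0.0423, and adjusted p = 0.117 with an estimated correlation. That list no longer passed with replicate number as a block (adjusted p = 0.0778), without DMSO replicate 1 (0.0542) or without FL3 replicate 1, 3 or 4 (0.0668, 0.0563 and 0.0522; lowest of its alternatives with the preset correlation 0.0346).

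Immediate early genes of the mouse line rose in 26 of 30 cases (27 adjusted over the list alone; median log2 1.82), with Fosl2 up 21.9-fold and Klf6 5.66-fold. Camera on immediate early genes gave adjusted p = 2.64e-10, and adjusted p = 0.0646 with an estimated correlation. Interferon-stimulated genes rose in 20 of 24 cases (20 higher and 1 lower adjusted over the list alone; median log2 1.64), such as the regulators Irf7 and Usp18, 11.7-fold and 9.52-fold, and the RNA sensor Ifih1 3.51-fold. Camera on interferon-stimulated genes gave adjusted p = 1.66e-07, and adjusted p = 0.0646 with an estimated correlation. ATF4 targets rose in 17 of 32 cases and fell in 3 (17 and 3 adjusted over the list alone), with the stress regulator Nupr1 up 56.5-fold, Atf3 9.78-fold and Ddit4 4.38-fold. Camera on ATF4 targets gave adjusted p = 0.000612, and adjusted p = 0.0862 with an estimated correlation. Of the list of the BCL2 family and other apoptosis regulators, 6 of 18 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.305). The pro-apoptotic Bbc3 and Pmaip1 were up 9.09-fold and 7.5-fold and the apoptosis inhibitor Birc2 3.87-fold. NF-kappaB targets rose in 17 of 30 cases and fell in 2 (19 and 2 adjusted over the list alone), with Gadd45b and Cflar up 3.96-fold and 3.93-fold and the cytokine subunit Ebi3 down 4.15-fold. Camera on NF-kappaB targets gave adjusted p = 0.00476, and adjusted p = 0.134 with an estimated correlation. ERK feedback genes rose in 7 of 11 cases (7 adjusted over the list alone), such as Egr2 8.99-fold, Phlda1 5.26-fold and Egr1 4.33-fold. Camera on ERK feedback genes gave adjusted p = 0.00476, and adjusted p = 0.148 with an estimated correlation. Substrates of nonsense-mediated decay rose in 13 of 29 cases and fell in 3 (13 and 3 adjusted over the list alone), with the snoRNA host gene Zfas1 up 6.54-fold. Camera on nonsense-mediated decay substrates gave adjusted p = 0.0157, and adjusted p = 0.0826 with an estimated correlation.

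Endoplasmic reticulum chaperone genes of the mouse line were 8 higher and 4 lower of 29 (8 and 4 adjusted over the list alone; camera adjusted p = 0.782), with a median of -0.06 and a mean of -0.02 on the log2 scale against an upward test. Sdf2l1, a subunit of a chaperone complex, fell 12.1-fold and Herpud1 and the disulphide isomerase P4hb rose 2.53-fold and 1.65-fold. B-cell receptor genes were 9 higher and 6 lower of 28 (9 and 6 adjusted over the list alone; camera adjusted p = 0.586), with the inhibitory receptor Cd22 down 9.75-fold. B-cell identity genes were 8 higher and 11 lower of 29 (8 and 11 adjusted over the list alone; camera adjusted p = 0.574), with Ms4a1, which encodes CD20, and the scaffold Bank1 down 4.85-fold and 4.12-fold and the repressor Bach2 up 3.2-fold. Plasma-cell genes were 3 higher and 5 lower of 15 (3 and 5 adjusted over the list alone; camera adjusted p = 0.432), with the transcription factor Prdm1 up 3.89-fold and the immunoglobulin joining chain Jchain down 15.8-fold (8 counts over the FL3 libraries). T and NK cell markers were 1 higher and 2 lower of 5 (1 and 2 adjusted over the list alone; camera adjusted p = 0.595), their median of 0.10 differing in sign from their mean of -0.17 and from the test. Trac fell 3.21-fold and Lck 1.55-fold. The higher one, Bcl11b, no longer passed without DMSO replicate 2 or 3 (adjusted p = 0.0984 and 0.134) or FL3 replicate 2 (0.112), with counts thinned (0.0685) or without ribosomal protein and mitochondrially encoded genes (0.0525; lowest of its alternatives 0.00916). Of 3 myeloid markers 1 fell, of 2 red-cell and platelet markers 1 fell and of 2 stromal markers 1 fell, and adjusted over each list alone 1 fell in each, with 1 red-cell or platelet marker higher. These single calls were Cd68, Hbb-bt and Col1a1. Cd68 no longer passed with DESeq2 (adjusted p = 0.0557) or with counts thinned (0.172), against 0.0113 to 0.046 on leaving out 1 library. Col1a1 no longer passed without DMSO replicate 1 or 3 (0.0693 and 0.076) or FL3 replicate 1 (0.0547), where the lowest value on leaving a library out was 0.0107. With replicate number as a block, the myeloid Adgre1 also passed as lower (log2 -0.60, adjusted p = 0.0132) and the platelet gene Itga2b as higher (log2 1.07, adjusted p = 0.00986). Adgre1 also passed as lower without FL3 replicate 4 (0.0296) and with counts thinned (0.0425), and the endothelial Pecam1 without DMSO replicate 1 (0.0438) and without ribosomal protein and mitochondrially encoded genes (0.0366). In all, 15 of 24 lists passed with the preset correlation, 7 higher and 8 lower; 6 passed with an estimated correlation, 11 having an unadjusted p under 0.05, and 20 passed with fry.

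The third comparison asked whether the lines responded alike. The cell cycle inhibitor CDKN1A rose 20.9-fold in the mouse line and 1.38-fold in MEC-1, a difference of 3.98 on the log2 scale (SE 0.192, 15 libraries, adjusted p = 2.71e-10). PTGIR differed by 7.05 (SE 0.389), rising in the mouse line and falling by 0.53 in MEC-1, and NQO1, a quinone reductase, by 4.13 (SE 0.352), rising 7.74-fold in the mouse line and falling 2.19-fold in MEC-1. RNASE6, an antimicrobial ribonuclease, also went opposite ways and differed by 4.39 (SE 0.299), and the interferon-induced MX2 by 5.08 (SE 0.513), with 3 counts over the DMSO and 87 over the FL3 libraries of the mouse line, a ratio of 29.4 (95% exact interval 9.72 to 145). On leaving out 1 library MX2 ran from 4.564 to 5.78, the highest without mouse DMSO replicate 3. On the other side, SDF2L1 differed by -4.12, the chemokine receptor ACKR3 by -3.91, the centriole gene TEDC1 by -3.86, the DNA repair gene RMI2 by -3.84 and JCHAIN by -3.68, the mouse line minus MEC-1. SDF2L1, ACKR3 and TEDC1 rose in MEC-1 (log2 0.57, 1.41 and 1.05) and fell in the mouse line (log2 -3.60, -2.57 and -2.86). In the interaction test 3789 of 8030 genes (47.2%) differed. Of these, 1888 had the higher log2 fold change in the mouse line and 1901 the lower. Of the 3789, 648 passed in opposite directions in the lines. On simulated data, with a far smaller share of genes changed, false calls of this test exceeded the share its threshold allows.

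Across the 8030 genes, which are not independent replicates, the log2 fold changes of the lines correlated with Pearson r of 0.373 and a Spearman correlation of 0.383 (jackknife SE of r over the 15 libraries 0.027). Of 2832 genes that passed in both lines, 77.1% had the same sign. Of these, 1159 rose in both, where independent lists would give 725.5, and 1025 fell in both against 637.9; 337 rose in MEC-1 and fell in the mouse line against 729.2, and 311 did the reverse against 634.7. Genes lower in both included LDHA and CDK4, and genes higher in both included MYC, JUN, KLF6, PMAIP1 and BBC3, as the log2 changes in each line show.

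Sterol synthesis genes differed most in median between the lines, by -2.15 on the log2 scale over 22 matched genes (camera adjusted p = 2.25e-11; adjusted p = 0.00541 with an estimated correlation). DNA replication and mitotic genes also had lower log2 fold changes in the mouse line, by medians of -1.39 and -1.12 (camera adjusted p = 1.16e-13 for each; adjusted p = 0.0304 and 0.0247 with an estimated correlation). ATF4 targets and interferon-stimulated genes responded higher in the mouse line, by medians of 1.27 and 1.20 (camera adjusted p = 3.87e-05 and 5.31e-05; adjusted p = 0.00541 and 0.0259 with an estimated correlation). Ribosomal protein genes and mitochondrially encoded messenger RNAs also had higher log2 fold changes in the mouse line, by medians of 0.69 and 1.08 over 74 and 6 matched genes. Camera gave adjusted p = 5.33e-08 and 0.00292 for these lists, and adjusted p = 0.364 and 0.282 with an estimated correlation. Immediate early genes differed by 0.85, NF-kappaB targets by 0.40 and ERK feedback genes by 0.37 (camera adjusted p = 0.000146, 0.0357 and 0.0481; adjusted p = 0.101, 0.267 and 0.18 with an estimated correlation). Ribosome assembly and nuclear respiratory chain genes differed by -0.35 and -0.30 (camera adjusted p = 0.0357 and 0.00706; adjusted p = 0.364 and 0.242 with an estimated correlation). The differences of ribosome assembly, ERK feedback and NF-kappaB genes depended on single libraries: the first no longer passed without MEC-1 DMSO replicate 3 (adjusted p = 0.0515), MEC-1 FL3 replicate 4 (0.0519), mouse DMSO replicate 2 (0.0555) or mouse FL3 replicate 1 (0.0514). ERK feedback genes no longer passed without MEC-1 DMSO replicate 3 (0.0515), MEC-1 FL3 replicate 4 (0.0542), or mouse FL3 replicate 1 or 2 (0.0599 and 0.0588), and NF-kappaB targets without MEC-1 FL3 replicate 4 (0.0542). The lowest values on leaving a library out were 0.00959, 0.0366 and 0.0228 for the 3 lists. MYC targets did not differ past the threshold (median -0.16, camera adjusted p = 0.0633), though they passed without MEC-1 FL3 replicate 2 (0.0439) or mouse DMSO replicate 2 (0.0452), and glycolysis genes did not (median -0.0022, camera adjusted p = 0.727). Endoplasmic reticulum chaperone genes did not differ past the threshold either (camera adjusted p = 0.127), but passed without mouse DMSO replicate 2 (0.0452). In all, 12 of 23 lists differed, 7 higher and 5 lower in the mouse line, and 5 with an estimated correlation; 34 of 100 splits drawn within the lines gave as many lists.

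**Figure D3:**
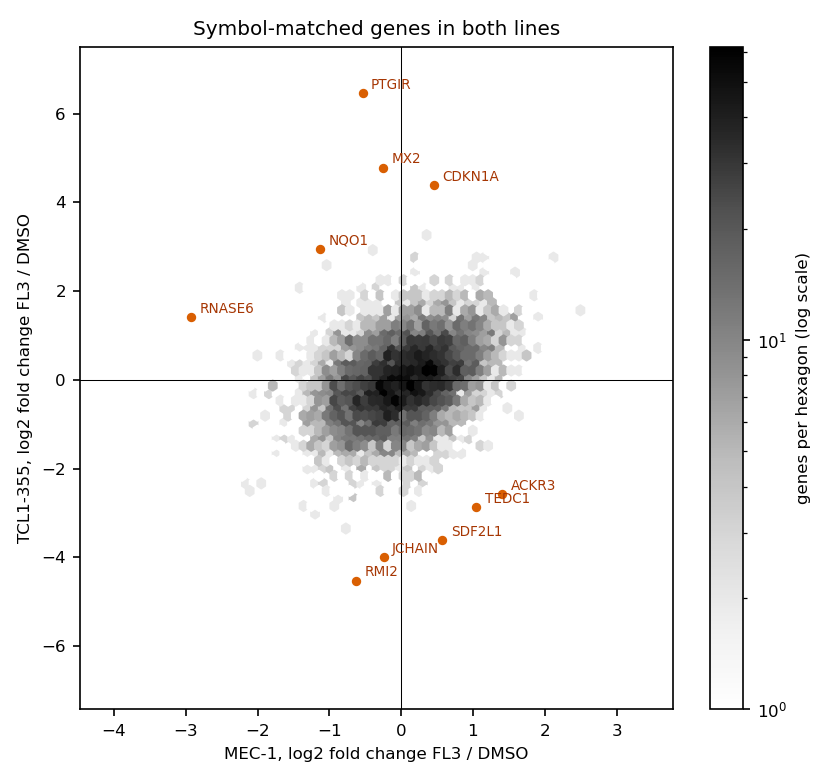
Log2 fold change (FL3 over DMSO) of the 8030 symbol-matched genes in MEC-1 (x axis) and the mouse line (y axis), as the number of genes per hexagon, with the 10 genes named for the difference between lines in orange. The correlation across genes is 0.373, and PTGIR lies highest among the named genes, at 6.45 in the mouse line and -0.53 in MEC-1.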

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

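The tests named below as scaling between libraries and the splits for the difference that part the mouse pairs were chosen after the results were seen; the other tests of explanations were written down before their values were seen. Some results stood out because 1 of 4 libraries lay far from the rest, others because the lines responded differently in the interaction test or in camera.

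Ribosomal protein and mitochondrially encoded transcripts fell together in MEC-1, with median log2 changes of -0.82 and -1.29. Neither list passed camera with an estimated correlation (adjusted p = 0.182 for each). With library size alone as the scaling, the higher of the 2 list medians was still -0.643. The choice between that scaling and TMM therefore does not account for the pattern. Both scalings are relative to the library, so a change in the total amount of messenger RNA was not tested. After thinning of all libraries to the smallest total, against the deeper FL3 libraries, the higher median was -0.829. Thinning keeps each gene's share of counts on average, so it could hardly have moved this median and does not decide on depth. The axis along which MEC-1 replicates vary within groups predicted 4.29% of the shift of the ribosomal protein genes. The prediction used the slope of fold change on axis loading over 11098 other genes, where fold change and loading correlated at -0.0859. Noise in the loadings flattens such a slope, so a small predicted share does not decide on that axis. Reads shared with pseudogenes of these families were not tested and stay open, as does a change in RNA quality with FL3. A response of the cells to FL3 may be what lowered them, a hypothesis found and tested on the same libraries.

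Replicates of the mouse line spread along 1 axis that took 64% of the variance within groups, against 27% for the first such axis in MEC-1. Loadings of the axes of the 2 lines correlated across 8030 genes (size of r 0.319), a value consistent with an axis of library preparation or cell state that both lines share; ribosomal protein genes had a median loading at percentile 88.6 in the mouse line and 74.4 in MEC-1. Library depth cannot be told apart from this axis: scores and log2 totals of 7 libraries correlated with r of 0.688 (exact permutation p = 0.0972, 144 permutations within groups) and rho of 0.786 (exact p = 0.0417). Without the 2 libraries whose scores lay farthest from the median score, r was 0.528. For GC content of the last 500 bases of the human transcript of the same symbol (8825 of 10475 genes), rho was -0.282, between the bounds set in advance, so it stays open too. No biological explanation was tested, since the design gives none for replicates.

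The MYC transcript rose while the MYC target list fell in both lines. Camera on the full list with an estimated correlation gave adjusted p = 0.0796 in MEC-1, which did not pass, and 0.0064 in the mouse line. The choice of scaling, TMM or library size, does not account for these opposite directions: with library size alone, MYC was at 1.30 in MEC-1 and 1.35 in the mouse line and the higher of the target medians at -0.538 on the log2 scale. Neither do members shared with other lists, such as glycolysis or DNA replication: over the 33 members that no other list holds, the larger camera adjusted p of the lines was 3.08e-05, and 26 fell and 4 rose in MEC-1, 28 fell and 2 rose in the mouse line (adjusted p = 0.0491 and 0.0093 with an estimated correlation). These values are consistent with a MYC transcript that rises without its targets following, for which MYC protein, not measured here, would be the next measurement.

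Whether regrouping the libraries could give counts as large was asked of each count. For genes in MEC-1, 1 of 35 splits, the real one, gave 7006 and the highest of the others 0. In the mouse line 1 of 35 gave 5548 genes and the highest other 0. Every other split mixes FL3 and DMSO libraries in at least 1 group, so the FL3 response widens the spread and lowers the count. These splits show that the counts follow the real groups, but not how many genes chance alone would give. For the genes that differ between lines, 1 of 100 splits drawn within each line gave 3789 and the highest other 2395; 10 of the 99 others kept the real groups in 1 line, and the highest of the rest was 1146. Among 100 drawn from the 280 splits that also part the 3 numbered pairs of the mouse line, 1 gave 3789 and the highest other 3578. Of the others, 12 kept the real groups in 1 line, and the highest of the rest was 1137. A split that keeps the real groups in 1 line sets the FL3 response of that line against mixed libraries. The splits are thus not draws from lines with equal FL3 responses, and neither set can exclude chance for this count. For the number of lists in MEC-1, 4 of 35 splits gave at least 14, the highest other 15, so chance is not excluded; the 16 splits that exchange 1 library per group gave 9 to 15 lists, and the 18 evenly mixed ones a median of 0 and at most 9. For lists in the mouse line, 1 of 35 splits gave 15 and the highest other 14, and the real count was itself 14 with replicate number as a block. Of the 8 splits that part the 3 numbered pairs of the mouse line as the real one does, the highest other gave 0 genes and 13 lists, and 8 splits are too few for a share under 0.05. For the lists that differ between lines, 34 of 100 splits gave at least 12, or 47 of 100 that part the pairs, with a highest other of 19 in each set, so chance is not excluded.

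Among 280 groups of 4 values of a gene and 15 of a library measure, 18 had a library whose gap to its nearest neighbour, as a share of the range, exceeded Dixon's critical value at the 95% level, 6.1% where chance gives about 5%. In MEC-1 with DMSO, ZBTB10 was 6.39 CPM in replicate 4 against 9.31 to 9.6 (gap 0.91 of the range), ACHE 3.39 in replicate 2 against 1.16 to 1.54 (0.833), RPL3 581 in replicate 2 against 748 to 780 (0.84), TYMS 232 in replicate 3 against 212 to 215 (0.846) and BTG1 477 in replicate 2 against 420 to 428 (0.848). In MEC-1 with FL3, CDK4 was 123 CPM in replicate 1 against 106 to 108 (0.853), CDC6 196 in replicate 1 against 174 to 176 (0.909) and SMC4, which overlaps 2 genes on its strand, 1230 in replicate 3 against 1430 to 1470 (0.855). In the mouse line with FL3, Rsph1 was 0.337 CPM in replicate 1 against 0 in the others (1), Myc 220 in replicate 1 against 104 to 122 (0.845) and Nuf2 24.1 in replicate 3 against 21.3 to 21.7 (0.887). In replicate 2 of that group, Bcl11b was 15.5 CPM against 7.22 to 8.09 (0.894) and Itga2b 13.3 against 5 to 6.07 (0.871). In replicate 4 of that group, Ccnd2 was 1120 against 893 to 916 (0.896), Ndufs6 101 against 84.1 to 86.7 (0.85), Tk1 30.5 against 22.4 to 23.6 (0.853), Nme1 133 against 109 to 112 (0.88) and Cd22 12.2 against 5.87 to 6.41 (0.915).

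Of 40 genes named in both lines or for the difference, 28 responded differently in the edgeR interaction test. Leaving aside the 10 chosen for the size of their difference, this was 18 of 30, where 47.2% of all genes tested differed; values are log2 changes of the mouse line minus MEC-1. Of the genes fixed in advance, EIF4E differed by -0.44, PDCD4 by -0.46, BCL2 by -0.79, BCL2L11 by -2.30, CDK4 by -0.77, BTK by 0.97 and TXNIP by 2.0. BCL2L11 rose in MEC-1 and fell in the mouse line. Of list members, RPL3 differed by 0.71, TYMS by -0.89, HERPUD1 by 0.36, JUN by 2.87, KLF6 by 0.72, PMAIP1 by 1.66, BBC3 by 1.53, SLAMF7 by -3.10, LCK by 0.97, TRAC by -1.0 and COL1A1 by -3.02. Of the genes named for the difference, SDF2L1 differed by -4.12, ACKR3 by -3.91, TEDC1 by -3.86, RMI2 by -3.84, JCHAIN by -3.68, CDKN1A by 3.98, NQO1 by 4.13, RNASE6 by 4.39, MX2 by 5.08 and PTGIR by 7.05. Lists differed in camera with median differences of 0.69 for ribosomal protein, -0.35 for ribosome assembly, 1.27 for ATF4 target, -1.39 for DNA replication, -1.12 for mitotic, 0.40 for NF-kappaB target, 0.85 for immediate early, 0.37 for ERK feedback, -2.15 for sterol synthesis, -0.30 for nuclear respiratory chain, 1.08 for mitochondrially encoded and 1.20 for interferon-stimulated genes. With an estimated correlation, 5 of these lists still differed, those of ATF4 targets, DNA replication, mitosis, sterol synthesis and interferon-stimulated genes. The others were lost: ribosomal protein (adjusted p = 0.364 with an estimated correlation), ribosome assembly (0.364), NF-kappaB target (0.267), immediate early (0.101), ERK feedback (0.18), nuclear respiratory chain (0.242) and mitochondrially encoded genes (0.282).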

How the results depend on the processing

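Thinning of counts and leaving out ribosomal protein and mitochondrially encoded genes were chosen after the results were seen; the other alternatives were planned. No gene that passed in either line changed its direction under any alternative run for that line (0 sign changes in each). Counts of changed genes ran from 6224 to 7750 in MEC-1 and from 4453 to 6794 in the mouse line except with glmTreat against a fold of 1.5, which left 2472 and 2921 since it asks for larger changes. The highest value in the mouse line, 6794, came from the replicate block, which gave 7186 in MEC-1. There, libraries of the same number correlated at 0.051, 0.16, 0.034 and -0.0061, which gives no clear sign of pairing by number. Whether they were paired is not given in the sources used here. Leaving out 1 library gave 6609 to 7013 genes in MEC-1, 4453 to 5496 in the mouse line and 3403 to 3853 for the difference between lines, whose other alternatives gave 3357 to 4535.

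With an estimated correlation, 0 lists passed in MEC-1, 6 in the mouse line and 5 for the difference, since camera then allows for the correlation found between members. Lists that passed numbered 13 to 14 in MEC-1, 14 to 16 in the mouse line and 9 to 13 for the difference under the other camera alternatives. The correlation of the lines across genes was 0.411 with at least 10 CPM, where fewer genes enter, and 0.356 to 0.383 under the other alternatives. Genes that passed in both lines in the same direction numbered 1817 to 2647 against 2184.

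The values that turned in sign belong to genes that had not passed. Leaving out 1 library, BTK in MEC-1 ran from -0.15 to 0.20 and CCND2 from -0.059 to 0.11 on the log2 scale; in the mouse line, Eif4a1 ran from -0.94 to 0.05, Pdcd4 from -0.19 to 0.0029, Mcl1 from -0.051 to 0.015 and Itgam, a myeloid marker, from -0.17 to 0.36. With counts thinned, BTK was at -0.066; these genes changed by less than their SE, and the cause was not tested further. In the mouse line, DMSO replicate 1 moved Eif4a1 to 0.05 when left out and DMSO replicate 2 moved Pdcd4 to 0.0029. Depth, spread between libraries and their number together limit the smaller changes: on simulated data, 8.96% of 1.5-fold changes were recovered in the mouse line and 51.5% in MEC-1. A fold under 2 that did not pass is therefore not shown to be absent. The simulation changed a far smaller share of genes than passed here and drew each gene separately, so these shares need not hold for the real data. Requiring at least 10 CPM left out some rare genes, for which that alternative gives no value.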

Other observations

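The lists in this part were chosen after values of single genes had been seen, so their tests describe these libraries and are not independent evidence; no explanation was tested for them. Targets of NRF2, the regulator of the antioxidant response, rose in 10 of 10 cases in the mouse line (median log2 2.24), such as heme oxygenase Hmox1 5.64-fold, Nqo1 7.74-fold, Gclc, of glutathione synthesis, 4.06-fold and thioredoxin reductase Txnrd1 3.92-fold (camera adjusted p = 7.13e-06; adjusted p = 0.0134 with an estimated correlation). In MEC-1 they fell in 6 of 9 cases (median log2 -0.63), with the ferritin genes FTL and FTH1 down 2.36-fold and 2.5-fold. GCLC, TXNRD1 and SLC7A11 did not pass there (adjusted p = 0.233, 0.0688 and 0.281). Ftl1 of the mouse line was rare, at 3.659 CPM with DMSO against 1600 for FTL in MEC-1. Camera on NRF2 targets in MEC-1 gave adjusted p = 0.0104, and adjusted p = 0.139 with an estimated correlation. Over the 6 matched genes the lines differed (camera adjusted p = 3.76e-06; adjusted p = 0.0137 with an estimated correlation). GTPases induced by interferon rose in 6 of 8 cases in the mouse line, for example Gbp2 8.23-fold and Igtp 6.3-fold (camera adjusted p = 0.00144; adjusted p = 0.0504 with an estimated correlation). In MEC-1, 4 of 5 GTPase genes on this list fell, namely GBP1, GBP3, GBP4 and IRGM (camera adjusted p = 0.0965). Whether each of them is induced by interferon in human cells was not tested. GBP1, GBP3 and IRGM were rare, at 4.711, 6.027 and 6.216 CPM with DMSO, and GBP2, at 48.1 CPM, rose 1.35-fold.

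Genes of the circadian clock rose in 8 of 10 cases in MEC-1, among them the nuclear receptor NR1D2 6.04-fold and PER1 3.47-fold (camera adjusted p = 0.00156; adjusted p = 0.0762 with an estimated correlation), and in 6 of 9 cases in the mouse line, with Dbp up 4.37-fold and Nr1d2 2.75-fold (camera adjusted p = 0.00869; adjusted p = 0.0504 with an estimated correlation). The difference between lines did not pass (camera adjusted p = 0.805). KLF transcription factors rose in 6 of 9 cases in MEC-1 and 8 of 11 in the mouse line, with KLF3 up 2.82-fold in MEC-1 and 6.87-fold in the mouse line (camera adjusted p = 0.016 and 3.79e-05; adjusted p = 0.11 and 0.0262 with an estimated correlation). The lines differed, with higher log2 fold changes in the mouse line over 9 matched genes (camera adjusted p = 0.00733; adjusted p = 0.041 with an estimated correlation). Genes of the mitochondrial ribosome fell in 41 of 73 cases and rose in 10 in MEC-1, and fell in 49 of 75 and rose in 1 in the mouse line, such as MRPS27 2.01-fold in MEC-1 and Mrpl18 3.05-fold in the mouse line (camera adjusted p = 0.00379 and 3.14e-08; adjusted p = 0.11 and 0.0134 with an estimated correlation). Over 71 matched genes the log2 fold changes were lower in the mouse line (camera adjusted p = 0.00655; adjusted p = 0.041 with an estimated correlation). Counts of small noncoding RNAs fell in 5 of 5 cases in MEC-1 (median log2 -3.03), with the Y RNA RNY4 down 8.18-fold and the vault RNA VTRNA1-1 9.13-fold (camera adjusted p = 0.00179, and 0.0762 with an estimated correlation). RNU4ATAC, the most abundant of them at 460.1 CPM with DMSO, fell 1.34-fold. The kit primes at the 3′ end of messenger RNAs, which these are not, so their counts may not follow their levels.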
